A study of Arabidopsis thaliana with 99 samples.

How the data were processed

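Transcript levels of Arabidopsis thaliana were measured with a custom Agilent array, hybridised with Cy3-labelled polyadenylated RNA in 1 channel. Per the labels, 99 arrays fell into 33 groups of 3 biological replicates, 16 of them organs or stages and 17 of them seedlings or plants under light or stress conditions. Per the file headers, each array carried 34262 distinct probes besides 153 negative and 1264 positive control spots. Of these probes, 26649 stood for annotated loci, 5876 for small open reading frames (sORFs) outside annotated genes, 1446 for transcribed units known from cDNA, and 291 carried several names. Of the annotated loci, 26171 were in the table that pairs loci with symbols and 10299 had a symbol. The file notes a risk of cross-hybridisation for 561 annotated, 518 sORF and 23 cDNA probes. Positions are those the probe annotation prints, on the genome build that the file headers name.

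Per the file headers, scanner signals are intensities that the authors obtained with Agilent Feature Extraction 9.5.3.1, with spatial detrending, background subtraction method 7, surrogate values for dim spots and no scaling between arrays. The raw spot and local background brightness (intensity, without normalization) and the flags per spot, of unit other, were taken per the file headers too. A spot counts as well above background where the background-subtracted signal exceeds the local spread by the multiple the software sets. The deposited matrix holds intensity values on a linear scale, which the authors had brought to 1 common distribution over the 99 arrays (quantile normalization), with medians of 113.2 to 113.4. The Spearman correlation of each of its columns with the scanner signal of that array was 1. The extraction protocol was an edited one on the slide of Silique 1, Flower 1 and Stem 1. Stress and seed arrays were read on 1 scanner and all others on another. The labels also name the affy package, without a version or a role.

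Scanner signals were converted to log2 and the 75th percentile of the probes other than controls was subtracted from each array, so that 0 marks this percentile. Each probe other than controls was taken as 1 gene, and the 291 probes with several names were left out of the tests. A gene was tested where it was well above background on all 3 arrays of at least 1 group of its experiment. Linear models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the data.table package (1.17.8), and figures were drawn in python 3.11.15. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison and an absolute log2 fold change of at least 1. All adjusted p-values for single genes come from limma with this method.

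Each experiment had its own fit. The stress fit held 27 arrays in 9 groups, 23892 genes and 18 residual degrees of freedom, with a median residual SD of 0.201 (log2). The white light fit held 12 arrays in 4 groups, 20394 genes and 8 degrees of freedom, with a median SD of 0.462. The monochromatic light fit held 12 arrays in 4 groups, 20349 genes and 8 degrees of freedom, with a median SD of 0.289. The seed fit held 9 arrays in 3 groups, 22971 genes and 6 degrees of freedom, with a median SD of 0.249. The organ fit held 48 arrays in 16 groups, 27805 genes and 32 degrees of freedom, with a median SD of 0.396. Dry seed and both imbibed stages served in the seed fit and, as organs, in the organ fit. A gene was termed organ-highest where it exceeded each of the 15 other organs at least 2-fold and the largest of its 15 p-values passed the adjustment.

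The samples, comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. Gene lists covered ABA and drought response, CBF and cold response, callus and regeneration, cell cycle, chlorophyll biosynthesis, circadian clock, cytosolic ribosomal proteins, dark and shade expressed genes, flavonoid biosynthesis, floral organ identity, germination and reserve use, heat shock, jasmonate, mature pollen, photomorphogenesis regulators, photosynthesis, reference genes, root, secondary cell wall, seed coat and endosperm, seed storage and late embryogenesis, senescence, sodium transport and proline and tapetum and pollen wall, with 373 entries for 370 loci, of which 366 had a probe of their own. Lists were compared with all other genes by camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over all lists and comparisons, and beside it with an estimated correlation and with fry. At the estimated correlation 8 of 720 list tests passed, of which 2 concern lists not counted in their experiment (photomorphogenesis regulators at 6 h of cold, adjusted p = 0.0494, and germination at 6 against 2 h of salt, adjusted p = 0.0494). The lists hold well-studied genes chosen from general knowledge. The mean of a list had another sign than its median and camera direction for sodium and proline at 6 h of salt (mean −0.0694, median 0.121), the clock at 6 h of heat (−0.056 and 0.756), photomorphogenesis regulators in red light (−0.114 and 0.259), reference genes at 24 h of imbibition (−0.0259 and 0.191) and floral identity in buds (−0.239 and 0.308).

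In each comparison up to 4 called members per list were named by the size of their change. Besides them, the 4 genes with a symbol and the largest rise and the 4 with the largest fall were eligible, provided that the groups did not overlap array by array and that all arrays of both groups were well above background. Per organ the 3 genes with the widest margin over the next organ were eligible, and per experiment 2 rising and 2 falling sORF features. Where 0 of 3 arrays of the dimmer group were well above background, a fold is given as "at least", computed against the mean, over the arrays of that group, of the larger of the measured signal and the lowest signal well above background on the array. Where 1 or 2 of 3 arrays were, their number is given. Unless a number of arrays is given, all 3 arrays of both groups were well above background.

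Precision is limited by the 3 arrays per group. Replicate numbers were checked for pairing by correlating residuals of arrays with 1 number across groups. The correlation was above 0.1 in all 18 pairs for white light (0.233 to 0.855, median 0.562) and in all 9 pairs for seeds (0.105 to 0.229, median 0.168), so that these numbers pair the samples. In the monochromatic (median 0.366) and organ (−0.00288) fits some pairs lay lower, and the numbers were taken as shared names only. In the stress fit 100 of 108 pairs lay above 0.1 (median 0.222) and all 27 arrays were closest to their own number, which marks the scan day there. Slides (26) and scan days (12, read from the headers as an order without dates) served as batches. Comparisons were repeated within each slide or scan day that held both groups, and, added after the results were seen, genes called without a scan day were compared on it.

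Calls were tested on simulated data drawn from normal distributions with the mean and spread of each gene, in which 200 genes were shifted. At a 4-fold change 92% of 50 genes were called for 2 h of drying, 52% for 1 h of white light, 92% for red light, 86% for imbibition of 24 h and 78% for the juvenile rosette, with 2 to 9 false calls among all genes tested. Organ-highest genes were recovered in 88% with 0 false calls.

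Alternatives covered quantile normalization, the median in place of the 75th percentile, normexp background correction with an offset of 50, the deposited values, no filter on dim probes, every probe by itself, slide as a random or fixed block, replicate number as a block, 1 fit over all 99 arrays, other detection rules and leaving out each array. Scan day as a block, slide as a fixed block in the light and organ fits, leaving out all arrays numbered 3 and leaving out the 1 h arrays were added after the data had been seen. The setting of every probe by itself only added the probes with several names to the tests. No sample was left out of the values given. The exact probe sequences were not used, so that cross-hybridisation rests on the note in the files.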

Results

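With 99 arrays, 3 in each of 33 groups, the precision of each value is limited. Soil-grown plants kept in long days at 22 °C gave rosettes of 3 ages (Young_Rosette, juvenile; Rosette, adult; Old_Rosette, senescent), stems, cauline leaves, closed buds (Young_Bud), buds with visible petals (Bud), open flowers, and siliques with white (Young_Silique), green (Silique) or ripe seeds (Old_Silique, 2 months old and yellowing). Roots and callus came from culture, and seeds were sampled dry (after-ripened for 4 weeks) or after 24 and 48 h of imbibition in light. Stress samples were 2-week-old plants taken before (Control) and after 2 and 6 h of drying on filter paper, 200 mM NaCl, 37 °C or 2 °C. White light samples were seedlings etiolated for 3 days and given 0, 1, 6 or 24 h of light. Monochromatic light samples had grown for 6 days in the dark or in continuous red, blue or far-red light. The 75th percentile of the signal ranged from 194.6 to 3314 units per array (median 1180), and 52.7% to 78.8% of probes were well above background (median 64.9%), against 0% to 2.61% of negative controls. Expression is given as log2 signal minus the 75th percentile of the array, as mean ± SD of n = 3, and changes with the standard error (SE) of the fit, as fold or, after "by", as log2 fold change. Of each gene list, the members that rose or fell past the threshold are counted. P-values measure the spread between these samples, part of which may be technical.

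Which annotated genes and sORFs were expressed was asked over all groups. On all 3 arrays of at least 1 group, 24838 annotated loci (93.2%), 1220 cDNA units (84.4%) and 2016 sORF features (34.3%) were well above background. In all 33 groups, 12851 annotated loci and 147 sORF features were, and in a single group 733 and 512. The median signal of the sORF probes was 2.31 units against 277 for annotated loci. Between 271 (24 h of white light) and 1063 (Young_Silique) sORF features were detected per group. Of the detected features, 897 were seen in organ groups only and 145 in condition groups only. In at least 1 comparison, 1855 of the 2016 detected sORF features and 24015 annotated loci were called. By the significance flag of the scanner software 4108 sORF features were detected, so that their number depends on the rule.

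**Figure D1:**
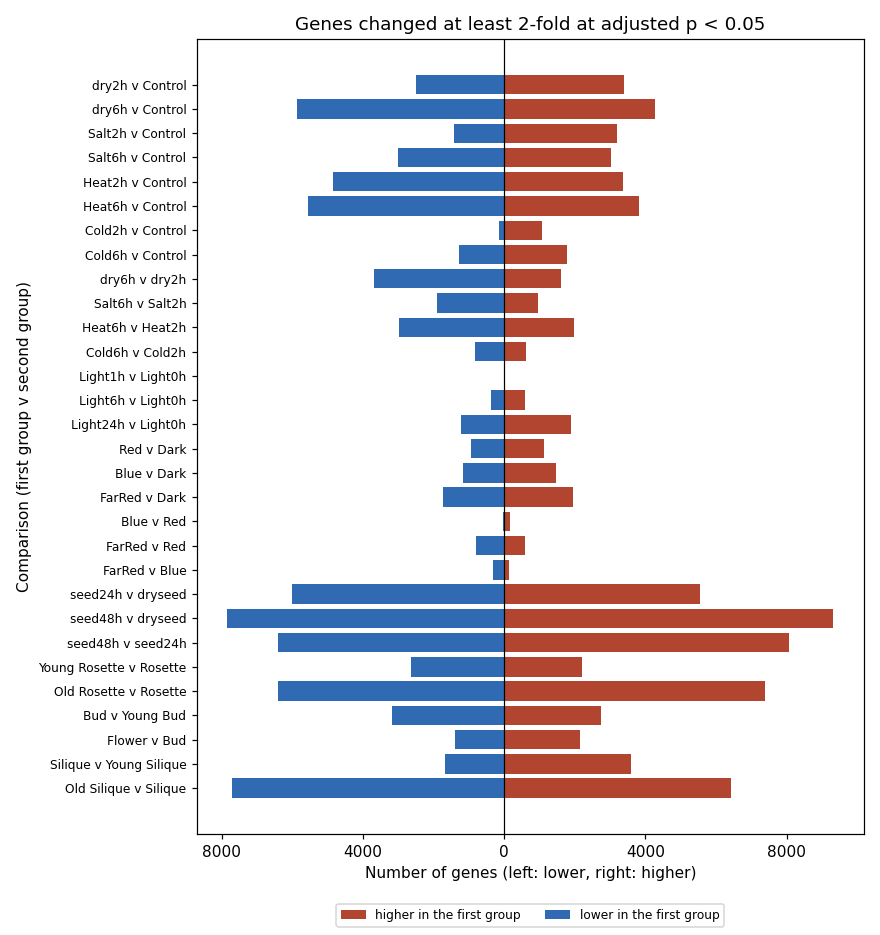
Number of genes past the threshold in each of 30 comparisons (bars to the right, higher in the first group; bars to the left, lower), n = 3 arrays per group. Counts run from 0 for 1 h of white light to 17152 (9317 higher and 7835 lower) for seeds imbibed for 48 h against dry seeds.

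The stress series asked which transcripts responded to drying, salt, heat and cold. No untreated plants were sampled at 2 or 6 h, so that each comparison with Control also holds elapsed time. After 2 h of drying, MAPKKK18 (AT1G05100) rose from −3.78 ± 0.16 to 5.25 ± 0.18, 522-fold (log2 9.03, SE 0.19, adjusted p = 5.3e-18). ABR1 (AT5G64750) rose 462-fold (log2 8.85, SE 0.29). The glucosinolate gene AOP2 (AT4G03060) fell by 5.03 (SE 0.36). All 23 ABA-response genes rose (camera up, adjusted p = 5.19e-19, adjusted p = 0.0494 with an estimated correlation), among them LTI65 (AT5G52300) 365-fold (log2 8.51, SE 0.34), NAC019 (AT1G52890) 305-fold (log2 8.25, SE 0.37) and the phosphatase HAI1 (AT5G59220) 72-fold (log2 6.17, SE 0.15). 18 of 20 CBF and cold-response genes rose and 2 did not pass (camera up, adjusted p = 3.08e-11, adjusted p = 0.0958 with an estimated correlation). 10 of 11 jasmonate genes rose and 1 did not pass (camera up, adjusted p = 2e-07, adjusted p = 0.162 with an estimated correlation), with JAZ1 (AT1G19180) up 61-fold (log2 5.93, SE 0.22). 11 of 26 heat shock genes rose, 1 fell and 14 did not pass (camera up, adjusted p = 0.00576, adjusted p = 0.615 with an estimated correlation), and DREB2A (AT5G05410) rose 85.2-fold (log2 6.41, SE 0.21). In all stress lists named here but 1, the ABA list at 2 h of cold, the counts adjusted over the list alone were those over all genes tested. Of 23892 genes tested, 3396 were higher and 2503 lower at 2 h.

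After 6 h of drying, LTI65 reached 5.86 ± 0.22, 1930-fold (log2 10.91, SE 0.34, adjusted p = 1.8e-16) above the control, LEA4-5 (AT5G06760) rose 1390-fold (log2 10.44, SE 0.49) and the oxidase gene CYP76C2 (AT2G45570) by 10.14 (SE 0.46). The growth-related EXPA8 (AT2G40610) fell from 4.48 ± 0.04 to −2.61 ± 0.31, and PRE1 (AT5G39860) fell by 6.56 (SE 0.29). All 23 ABA-response genes rose (camera up, adjusted p = 2.04e-14, adjusted p = 0.0828 with an estimated correlation). 18 of 20 CBF and cold-response genes rose, 1 fell and 1 did not pass (camera up, adjusted p = 3.49e-07, adjusted p = 0.196 with an estimated correlation). 20 of 26 heat shock genes rose and 6 did not pass (camera up, adjusted p = 4.7e-08, adjusted p = 0.319 with an estimated correlation), with HSP17.6A (AT5G12030) up at least 41.5-fold. 7 of 26 photosynthesis genes fell and 19 did not pass (camera down, adjusted p = 0.0164, adjusted p = 0.73 with an estimated correlation), with LHCB3 (AT5G54270) down by log2 −2.78 (SE 0.27) and RBCS2B (AT5G38420) by log2 −2.70 (SE 0.15). 3 of 9 sodium and proline genes rose, 1 fell and 5 did not pass (camera adjusted p = 0.183), with the proline gene P5CS1 (AT2G39800) up by 2.99 (SE 0.16) and the sodium transporter HKT1 (AT4G10310) down by log2 −2.66 (SE 0.21). In total 4272 genes were higher and 5868 lower, or 5957 and 4062 with arrays scaled to the median, which moved the median of all genes by 0.347.

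Salt for 2 h raised the glutaredoxin GRX480 (AT1G28480) from −4.58 ± 0.36 to 4.55 ± 0.19, 558-fold (log2 9.13, SE 0.24, adjusted p = 1e-16). ABR1 rose 281-fold (log2 8.13, SE 0.29), ERF1 (AT3G23240) 249-fold (log2 7.96, SE 0.30) and the calmodulin-like CML37 (AT5G42380) 218-fold (log2 7.77, SE 0.28). EXPA8 fell by 4.21 (SE 0.35) and the cell wall gene XTH13 (AT5G57540) fell by 3.86 (SE 0.34). All 11 jasmonate genes rose (camera up, adjusted p = 2.7e-09, adjusted p = 0.104 with an estimated correlation), with JAZ7 (AT2G34600) up 91-fold (log2 6.51, SE 0.42) and JAZ8 (AT1G30135) at least 20.1-fold. 22 of 23 ABA-response genes rose and 1 did not pass (camera up, adjusted p = 1.35e-20, adjusted p = 0.0478 with an estimated correlation). 17 of 20 CBF and cold-response genes rose and 3 did not pass (camera up, adjusted p = 2.02e-13, adjusted p = 0.0734 with an estimated correlation). 2 of 9 sodium and proline genes rose, 1 fell and 6 did not pass (camera adjusted p = 0.18), with P5CS1 up by 1.91 (SE 0.16). Counts were 3202 higher and 1419 lower, or 2909 and 2038 by the median (shift of all genes −0.14) and 2955 and 2074 by quantile normalization.

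After 6 h of salt GRX480 stood at 4.93 ± 0.30, 730-fold (log2 9.51, SE 0.24, adjusted p = 4.3e-17) above the control, and the embryo gene EM1 (AT3G51810) rose from −6.48 ± 0.87 to 2.42 ± 0.12, 477-fold (log2 8.90, SE 0.40). AOX1D (AT1G32350), a mitochondrial alternative oxidase, rose 252-fold (log2 7.98, SE 0.53). EXPA8 fell by 6.47 (SE 0.35) and PCC1 (AT3G22231) fell by 5.64 (SE 0.45). 20 of 23 ABA-response genes rose and 3 did not pass (camera up, adjusted p = 3.59e-17, adjusted p = 0.0605 with an estimated correlation). 20 of 26 heat shock genes rose and 6 did not pass (camera up, adjusted p = 1.67e-09, adjusted p = 0.237 with an estimated correlation). The ribosomal protein list moved downward as a set, and 1 of 15 ribosomal protein genes fell and 14 did not pass (camera down, adjusted p = 0.000101, adjusted p = 0.237 with an estimated correlation). HKT1 fell by 2.65 (SE 0.21), as it had in drying, while 1 of 9 sodium and proline genes fell and 8 did not pass (camera adjusted p = 0.591). In total 3036 genes were higher and 2993 lower.

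At 2 h of heat HSP23.6-MITO (AT4G25200) rose from −6.52 ± 0.05 to 8.25 ± 0.30, 27800-fold (log2 14.76, SE 0.45, adjusted p = 1.1e-16), APX2 (AT3G09640) 4750-fold (log2 12.21, SE 0.40), the factor HSFA2 (AT2G26150) 3100-fold (log2 11.60, SE 0.33) and the protease FTSH6 (AT5G15250) 928-fold (log2 9.86, SE 0.23). 25 of 26 heat shock genes rose and 1 did not pass (camera up, adjusted p = 2.41e-22, adjusted p = 0.0734 with an estimated correlation), with HSP21 (AT4G27670) up at least 33300-fold and HSP17.6A at least 17200-fold. AOP2 fell by 5.49 (SE 0.36) and NAC1 (AT1G56010) fell by 4.91 (SE 0.18). The sORF features NEW_TU_5799 (chromosome 5, 3526433 to 3526594, plus strand) and NEW_TU_1130 (chromosome 2, 3440277 to 3440390, plus strand) rose 178-fold (log2 7.48, SE 0.19) and 158-fold (log2 7.31, SE 0.18). Of 1080 sORF features tested, 432 were higher and 89 lower. Over all genes 3366 were higher and 4832 lower, or 4933 and 3131 by the median, whose shift was 0.341.

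At 6 h of heat HSP23.6-MITO was up 16700-fold (log2 14.03, SE 0.45), HSP18.2 (AT5G59720) 371-fold (log2 8.53, SE 0.23) and HSFA2 309-fold (log2 8.27, SE 0.33). All 26 heat shock genes rose (camera up, adjusted p = 2.44e-18, adjusted p = 0.103 with an estimated correlation). The cyclin CYCA1;1 (AT1G44110) fell by 6.21 (SE 0.19) and the iron transporter IRT1 (AT4G19690) fell by 5.88 (SE 0.31). 6 of 8 flavonoid genes fell and 2 did not pass (camera down, adjusted p = 0.0218, adjusted p = 0.52 with an estimated correlation), with LDOX (AT4G22880) down by log2 −4.69 (SE 0.25). 6 of 14 clock genes rose, 3 fell and 5 did not pass (camera adjusted p = 0.45), as LHY (AT1G01060) fell by 5.71 (SE 0.21) and RVE8 (AT3G09600) fell by 3.07 (SE 0.12), while PCL1 (AT3G46640) rose by 1.85 (SE 0.15) and GI (AT1G22770) by 1.78 (SE 0.16). Counts were 3818 higher and 5547 lower, or 6648 and 3646 by the median (shift 0.471).

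Cold for 2 h raised CBF1 (AT4G25490) from −4.48 ± 0.42 to 4.14 ± 0.29, 393-fold (log2 8.62, SE 0.44, adjusted p = 8.8e-12), CBF2 (AT4G25470) 389-fold (log2 8.61, SE 0.36), DREB1A (AT4G25480) 130-fold (log2 7.02, SE 0.32) and the calmodulin-like CML38 (AT1G76650) 95.3-fold (log2 6.57, SE 0.30). 17 of 20 CBF and cold-response genes rose and 3 did not pass (camera up, adjusted p = 7.53e-40, adjusted p = 0.00229 with an estimated correlation). 4 of 23 ABA-response genes rose and 19 did not pass, with 5 up and 0 down adjusted over the list alone (camera up, adjusted p = 0.00522, adjusted p = 0.511 with an estimated correlation), and 9 of 26 heat shock genes rose and 17 did not pass (camera up, adjusted p = 0.00448, adjusted p = 0.597 with an estimated correlation). Falls were few, with 157 genes lower and 1078 higher, and OFP16 (AT2G32100) fell by 1.85 (SE 0.27). After 6 h GolS3 (AT1G09350) had risen from −5.47 ± 0.43 to 2.08 ± 0.26, 187-fold (log2 7.55, SE 0.32), and CBF1 was up 277-fold (log2 8.12, SE 0.44). All 20 CBF and cold-response genes rose (camera up, adjusted p = 3.35e-30, adjusted p = 0.00656 with an estimated correlation). 9 of 14 clock genes rose and 5 did not pass (camera up, adjusted p = 2.92e-09, adjusted p = 0.0954 with an estimated correlation), among them PRR5 (AT5G24470) by 4.25 (SE 0.16) and FKF1 (AT1G68050) by 4.20 (SE 0.21). 11 of 23 ABA-response genes rose and 12 did not pass (camera up, adjusted p = 3.35e-05, adjusted p = 0.327 with an estimated correlation), and the antenna gene CAB2 (AT1G29920) rose 12.9-fold (log2 3.69, SE 0.20). P1R3 (AT3G29370) fell by 4.08 (SE 0.29) and LBD37 (AT5G67420) fell by 3.58 (SE 0.20). Counts at 6 h were 1788 higher and 1275 lower.

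**Figure D2:**
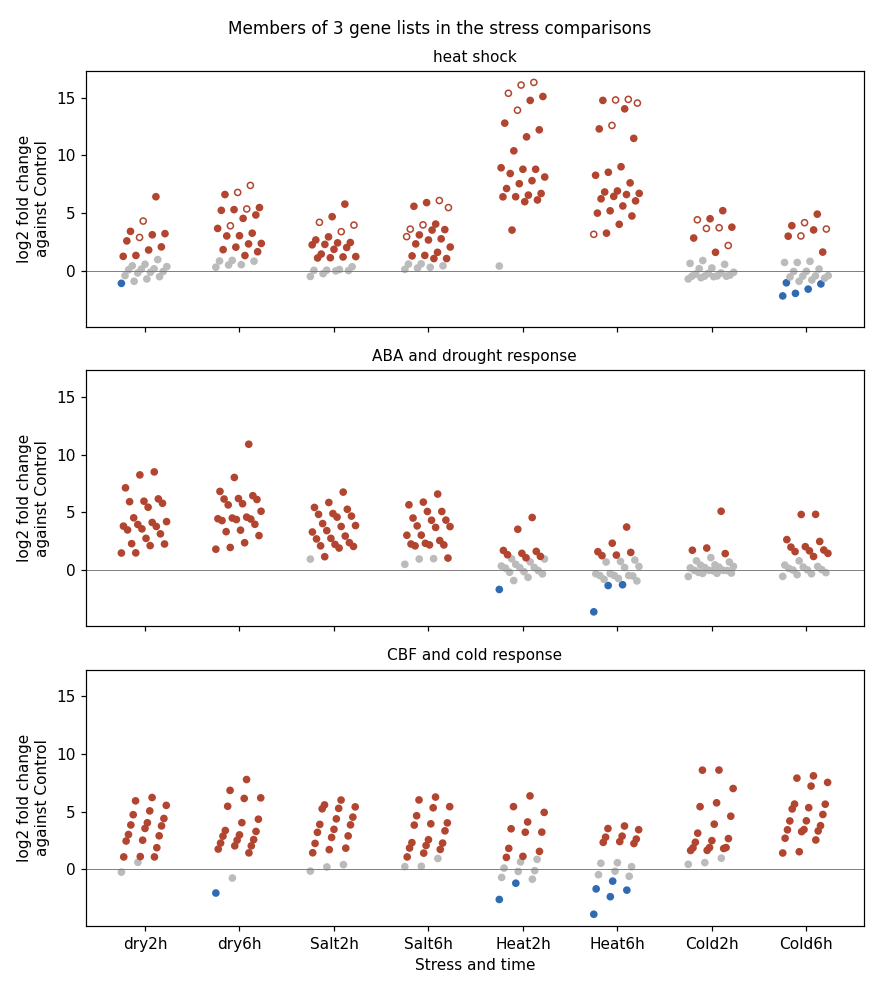
Log2 fold change against Control (vertical axis) of each member of the heat shock, ABA and drought, and CBF and cold lists in the 8 stress comparisons, n = 3 arrays per group. Red and blue points are called, grey points are not, and open points have 0 of 3 arrays well above background in the dimmer group, so that their height is a fitted value. At 2 h of heat 25 of 26 heat shock genes were called higher, and at 6 h of cold all 20 genes of the cold list.

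Whether the response changed between 2 and 6 h was tested as the difference of both times. In drying, NADP-ME1 (AT2G19900) rose further, from −3.24 ± 0.24 to 2.45 ± 0.66, 51.7-fold (log2 5.69, SE 0.38), and the cytokinin oxidase CKX4 (AT4G29740) fell by 3.65 (SE 0.18). 18 of 26 heat shock genes rose, 1 fell and 7 did not pass (camera up, adjusted p = 2.21e-07, adjusted p = 0.327 with an estimated correlation), while 6 of 23 ABA-response genes rose, 2 fell and 15 did not pass (camera up, adjusted p = 0.0026, adjusted p = 0.483 with an estimated correlation). Drying changed 1611 genes upward and 3672 downward, against 3642 and 1831 by the median (shift 0.377) and 2102 and 2572 by quantile normalization (shift 0.135). In salt, ACS11 (AT4G08040) rose 28.8-fold (log2 4.85, SE 0.33) and the kinase CRK36 (AT4G04490) 24.7-fold (log2 4.63, SE 0.33), while IRT1 fell by 3.80 (SE 0.31). Salt changed 958 genes upward and 1903 downward, 1414 and 1441 by the median (shift 0.193), and 1246 and 1536 by quantile normalization. In heat, HSFA2 fell by 3.32 (SE 0.33) and LHY by log2 −4.26 (SE 0.21), and PUM9 (AT1G35730) rose 36.9-fold (log2 5.21, SE 0.77). 1 of 26 heat shock genes rose, 12 fell and 13 did not pass (camera down, adjusted p = 0.00077, adjusted p = 0.516 with an estimated correlation). Heat changed 1988 genes upward and 2971 downward, or 2667 and 2460 by the median (shift 0.13). In cold, GolS3 rose 33-fold (log2 5.05, SE 0.32), RAS1 (AT1G09950) 20-fold (log2 4.32, SE 0.34) and GPT2 (AT1G61800) 16.8-fold (log2 4.07, SE 0.26), while ORA47 (AT1G74930) fell by 4.61 (SE 0.37). 11 of 20 CBF and cold-response genes rose and 9 did not pass (camera up, adjusted p = 4.21e-11, adjusted p = 0.0965 with an estimated correlation), with COR27 (AT5G42900) up by 3.24 (SE 0.16). 6 of 14 clock genes rose and 8 did not pass (camera up, adjusted p = 3.32e-09, adjusted p = 0.0954 with an estimated correlation), with FKF1 up by 1.95 (SE 0.21). Cold changed 609 genes upward and 820 downward, or 761 and 624 by the median (shift 0.133).

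In the reference list, 2 of 10 genes rose in each stress comparison, UBQ10 (AT4G05320) and GAPC1 (AT3G04120), with camera adjusted p from 0.103 to 0.91. UBQ10 rose by 1.66 (6 h of heat) to 3.88 (6 h of drying) and GAPC1 by 1.36 (6 h of heat) to 3.21 (6 h of cold), upward under each scaling tried, although GAPC1 stayed below 2-fold with normexp correction in both drying, both salt, the later heat and the earlier cold comparison. All stress comparisons shared the 3 Control arrays, which cannot be split, so that part of any excess overlap can come from them. Effects of 2 and 6 h of drying correlated across genes at 0.838 (simulated shared controls alone, 0.499), with a covariance of 1.84 (simulated 0.0305), and 2675 genes rose in both against 607 expected and 0 simulated. Effects of 2 h of drying and 2 h of salt correlated at 0.792, with 2230 genes higher in both against 455 expected. Those of 6 h of heat and cold correlated at 0.097 (covariance 0.127). Here 565 genes were higher in both (286 expected), 367 lower in both and 667 opposite. Of genes called without the arrays of 1 scan day, 95.5% to 99.6% had the same direction on that day (36 values), and 65.7% to 92.2% changed at least 2-fold there.

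The white light series asked how etiolated seedlings responded to light over time. At 1 h, limma called 0 of 20394 genes, with 158 at an unadjusted p below 0.05, and 0 in the 9 lists counted for this series. As sets, the clock (camera upward, adjusted p = 0.000101, adjusted p = 0.443 with an estimated correlation) and photomorphogenesis lists (adjusted p = 0.00501, adjusted p = 0.458 with an estimated correlation) moved upward. The photosynthesis list moved downward (adjusted p = 0.0429, adjusted p = 0.794 with an estimated correlation), and its direction turned with scan day as a block (adjusted p = 0.95). The 3 samples of 1 h differed: SIGE (AT5G24120) stood at −1.94, −2.53 and 3.13 (same numbers at 0 h −1.96, −2.60 and −2.35), HY5 (AT5G11260) at 0.96, 0.68 and 2.60, and PIL1 (AT2G46970) at 2.16, 2.23 and −2.87. In the 3 same-number pairs, 104, 127 and 1781 genes lay over 2-fold apart, so that the list shifts may rest on the third alone.

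**Figure D3:**
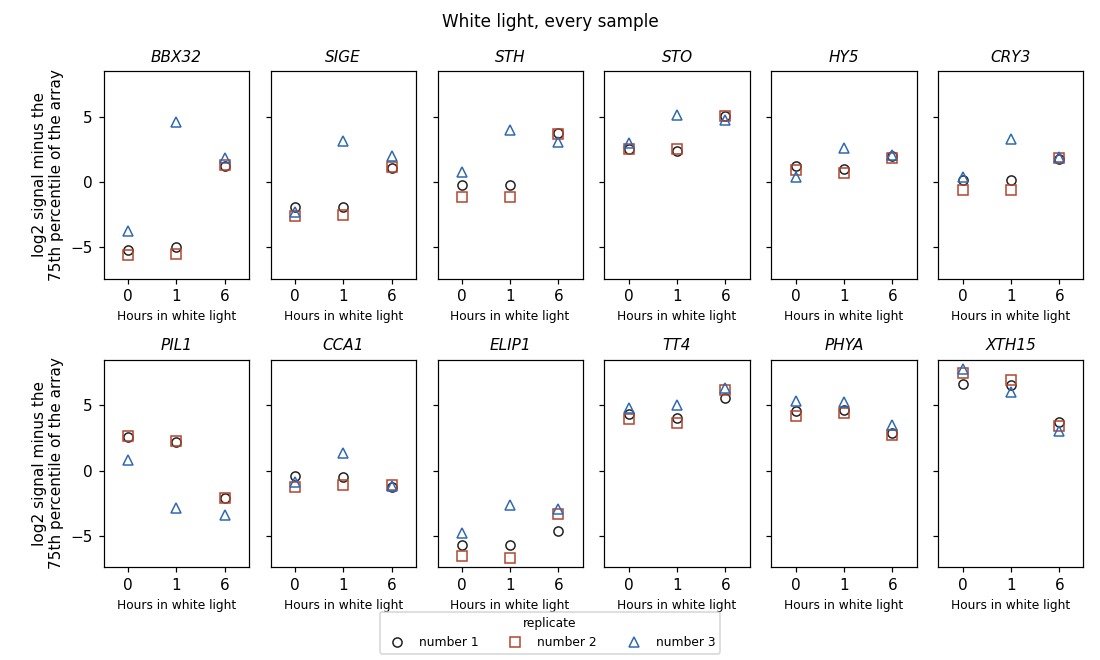
Log2 signal minus the 75th percentile of the array (vertical axis) of 12 light-related genes after 0, 1 and 6 h of white light, 1 symbol per sample, 3 samples per time. At 1 h the sample numbered 3 stood apart, for BBX32 at 4.57 against −4.98 and −5.57.

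At 6 h the thionin THI2.2 (AT5G36910) rose from −2.50 ± 0.54 to 4.51 ± 1.12, 128-fold (log2 7.0, SE 0.79, adjusted p = 0.001), FAH1 (AT4G36220) 57.2-fold (log2 5.84, SE 0.82) and MSRB6 (AT4G04840) 41.9-fold (log2 5.39, SE 0.31, adjusted p = 3.1e-05). The protochlorophyllide reductase gene PORA (AT5G54190) fell from 5.67 ± 0.53 to −0.63 ± 0.41, or log2 −6.30 (SE 0.61), and FLP1 (AT4G31380) fell by 4.71 (SE 0.39). All 8 flavonoid genes rose (camera up, adjusted p = 4.66e-11, adjusted p = 0.196 with an estimated correlation), with LDOX up at least 229-fold and DFR (AT5G42800) at least 54.9-fold. 4 of 26 photosynthesis genes rose and 22 did not pass, with 10 up and 0 down adjusted over the list alone (camera up, adjusted p = 6.52e-08, adjusted p = 0.483 with an estimated correlation), with CAB2 up 28.9-fold (log2 4.85, SE 0.84, 2 of 3 Light0h arrays well above background). 1 of 10 photomorphogenesis genes rose and 9 did not pass, with 5 up and 1 down adjusted over the list alone (camera up, adjusted p = 0.000885, adjusted p = 0.37 with an estimated correlation), with LZF1 (AT1G78600) up by 2.85 (SE 0.48). The calls of CAB2 and LZF1 ended with slide as a random block. 1 of 12 dark and shade genes rose, 3 fell and 8 did not pass, with 1 up and 8 down adjusted over the list alone (camera down, adjusted p = 0.000397, adjusted p = 0.359 with an estimated correlation), with XTH15 (AT4G14130) down by log2 −3.93 (SE 0.36) and PIF4 (AT2G43010) up by 2.31 (SE 0.24). 3 of 14 clock genes rose, 1 fell and 10 did not pass, with 7 up and 1 down adjusted over the list alone (camera up, adjusted p = 0.0033, adjusted p = 0.553 with an estimated correlation), with ELF4 (AT2G40080) up by 3.93 (SE 0.57). 2 of 13 chlorophyll genes fell and 11 did not pass, with 2 up and 2 down adjusted over the list alone (camera adjusted p = 0.373), the falls being PORA and PORB (AT4G27440), the reductases of etiolated seedlings. Called genes were 604 higher and 369 lower, in total 973, with 351 to 896 when 1 array was left out, 2296 with replicate number as a block and 209 with slide as a random block.

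At 24 h ECS1 (AT1G31580) rose from −2.89 ± 0.44 to 3.44 ± 0.27, 80.7-fold (log2 6.34, SE 0.42, adjusted p = 1.3e-05), THI2.2 183-fold (log2 7.52, SE 0.79) and the amylase CT-BMY (AT4G17090) 126-fold (log2 6.98, SE 1.04). PORA fell by 9.83 (SE 0.61, 2 of 3 Light24h arrays well above background). 11 of 26 photosynthesis genes rose and 15 did not pass, with 16 up and 0 down adjusted over the list alone (camera up, adjusted p = 8.55e-07, adjusted p = 0.511 with an estimated correlation). All 8 flavonoid genes rose (camera up, adjusted p = 1.22e-08, adjusted p = 0.237 with an estimated correlation), with LDOX up at least 319-fold. 9 of 12 dark and shade genes fell and 3 did not pass (camera down, adjusted p = 5.8e-05, adjusted p = 0.319 with an estimated correlation), with XTH15 down by log2 −5.12 (SE 0.36). 3 of 13 chlorophyll genes rose, 2 fell and 8 did not pass, with 6 up and 2 down adjusted over the list alone (camera adjusted p = 0.181), with PORB down by log2 −3.24 (SE 0.25). 3 of 10 photomorphogenesis genes rose, 1 fell and 6 did not pass (camera up, adjusted p = 0.0288, adjusted p = 0.542 with an estimated correlation), with HYH (AT3G17609) up by 2.86 (SE 0.44). Called genes were 1904 higher and 1234 lower, or 1616 and 1617 by the median (shift −0.136), in total 3138, 2055 to 2996 when 1 array was left out and 1489 with slide as a random block. The reference list had 0 of 10 genes called at each time. Of genes called without the arrays of the later of 2 scan days, 88.3% at 6 h and 93.4% at 24 h had the same direction on that day (55.9% and 66.5% at least 2-fold), while without the earlier day, which left 1 array of each group compared, 0 were called.

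The monochromatic series asked which transcripts differed between seedlings grown in 1 colour of light and in the dark. In red light, the cruciferin seed protein gene CRU3 (AT4G28520) fell from 6.55 ± 0.53 to 0.09 ± 0.50, a log2 change of −6.46 (SE 0.42, adjusted p = 1.9e-05), and the oleosin OLEO4 (AT3G27660) fell by 4.35 (SE 0.63). ESM1 (AT3G14210) rose from −4.03 ± 0.78 to 1.28 ± 0.79, 39.7-fold (log2 5.31, SE 0.68), and the ammonium transporter AMT1;2 (AT1G64780) 20.2-fold (log2 4.34, SE 0.35). 19 of 26 photosynthesis genes rose and 7 did not pass (camera up, adjusted p = 2.02e-13, adjusted p = 0.211 with an estimated correlation), with LHCA1 (AT3G54890) up by 3.46 (SE 0.30). 8 of 13 chlorophyll genes rose and 5 did not pass (camera up, adjusted p = 3.41e-07, adjusted p = 0.0882 with an estimated correlation), with HEMA1 (AT1G58290) up by 1.71 (SE 0.14). 1 of 13 dark and shade genes rose, 9 fell and 3 did not pass (camera down, adjusted p = 2.89e-05, adjusted p = 0.319 with an estimated correlation), with PIL1 down by log2 −4.34 (SE 0.62) and HFR1 (AT1G02340) by log2 −3.29 (SE 0.36). 1 of 9 photomorphogenesis genes rose, 1 fell and 7 did not pass (camera adjusted p = 0.939). Red light changed 1137 genes upward and 941 downward (2078 in total, 592 with normexp, 3527 with slide as a fixed block).

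In blue light, the aldolase FBA5 (AT4G26530) rose from −3.05 ± 1.09 to 4.92 ± 0.33, 251-fold (log2 7.97, SE 0.66, adjusted p = 2.9e-05), CT-BMY 46.6-fold (log2 5.54, SE 0.42) and THI2.2 45.8-fold (log2 5.52, SE 0.51), and CRU3 fell by 6.71 (SE 0.42). 19 of 26 photosynthesis genes rose and 7 did not pass, with 20 up and 0 down adjusted over the list alone (camera up, adjusted p = 3.24e-13, adjusted p = 0.211 with an estimated correlation). 5 of 9 photomorphogenesis genes rose and 4 did not pass (camera up, adjusted p = 0.00144, adjusted p = 0.196 with an estimated correlation), with SIGE up by 3.49 (SE 0.24) and HYH by 2.76 (SE 0.27). 4 of 6 flavonoid genes rose and 2 did not pass (camera up, adjusted p = 0.001, adjusted p = 0.343 with an estimated correlation), with F3H (AT3G51240) up by 2.61 (SE 0.43). 7 of 13 dark and shade genes fell and 6 did not pass, with 0 up and 8 down adjusted over the list alone (camera down, adjusted p = 0.000208, adjusted p = 0.359 with an estimated correlation). Blue light changed 1457 genes upward and 1168 downward (2625 in total, 1122 with normexp, 4353 with that block). In far-red light, FBA5 rose 153-fold (log2 7.25, SE 0.66), THI2.2 48.5-fold (log2 5.60, SE 0.51) and NdhU (AT5G21430) 27.8-fold (log2 4.8, SE 0.32), whereas PORA fell from 4.35 ± 0.33 to −0.70 ± 1.38 and the desaturase ADS1 (AT1G06080) fell by 4.23 (SE 0.34). All 6 flavonoid genes rose (camera up, adjusted p = 2.14e-05, adjusted p = 0.229 with an estimated correlation), with F3H up by 4.76 (SE 0.43) and TT4 (AT5G13930) by 4.61 (SE 0.59). 19 of 26 photosynthesis genes rose and 7 did not pass (camera up, adjusted p = 1.27e-10, adjusted p = 0.274 with an estimated correlation). 7 of 15 ribosomal protein genes rose and 8 did not pass (camera up, adjusted p = 0.00044, adjusted p = 0.588 with an estimated correlation). 6 of 13 dark and shade genes fell and 7 did not pass (camera down, adjusted p = 0.00525, adjusted p = 0.485 with an estimated correlation), with IAA19 (AT3G15540) down by log2 −4.04 (SE 0.37). Far-red light changed 1950 genes upward and 1737 downward (3687 in total, 1704 with normexp).

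Differences between colours were tested directly, at 0.17 (red), 1.16 (blue) and 0.53 (far-red) µmol per m2 per s. Colour, intensity and partly slide cannot be told apart here or against the dark. Among arrays 1 and 2 only red and blue shared a slide. Between blue and red light 164 genes were higher in blue and 42 lower (206 in total, 58 to 295 when 1 array was left out, 57 with normexp, 690 with slide as a fixed block), with SDR1 (AT3G61220) up 24.7-fold (log2 4.63, SE 0.52) and HFR1 10.5-fold (log2 3.40, SE 0.36), while LHCB3 was lower by log2 −1.67 (SE 0.20). 4 of 9 photomorphogenesis genes rose and 5 did not pass (camera up, adjusted p = 4.48e-12, adjusted p = 0.0427 with an estimated correlation), with HYH up by 2.43 (SE 0.27). 0 of 6 flavonoid genes passed, with 2 up and 0 down adjusted over the list alone (camera up, adjusted p = 0.00248, adjusted p = 0.367 with an estimated correlation). Between far-red and red light 601 genes were higher and 792 lower (1393 in total, 867 to 1651 when 1 array was left out). ELIP2 (AT4G14690) was higher at 3.02 ± 1.37 against −2.75 ± 0.24, 54.4-fold (log2 5.77, SE 0.55, adjusted p = 0.00019), CRU3 36.2-fold (log2 5.18, SE 0.42) and TT4 22.4-fold (log2 4.49, SE 0.59), while PORA was lower by log2 −3.71 (SE 0.59) and BGLU18 (AT1G52400) by log2 −3.33 (SE 0.34). 5 of 6 flavonoid genes rose and 1 did not pass (camera up, adjusted p = 3.02e-06, adjusted p = 0.196 with an estimated correlation), and 4 of 9 photomorphogenesis genes rose and 5 did not pass (camera up, adjusted p = 1.87e-05, adjusted p = 0.104 with an estimated correlation). Between far-red and blue light 135 genes were higher and 306 lower (441 in total, 122 to 699 when 1 array was left out), with CRU3 at 5.27 ± 0.64 against −0.16 ± 0.67, 43-fold (log2 5.43, SE 0.42). 4 of 6 flavonoid genes rose and 2 did not pass, with 5 up and 0 down adjusted over the list alone (camera up, adjusted p = 5.78e-06, adjusted p = 0.211 with an estimated correlation). In each comparison of this series 0 of 10 reference genes were called. All light groups shared the 3 dark arrays. Effects of red and blue light correlated at 0.876, with a covariance of 0.586 (simulated 0.0469). In both, 850 genes rose against 81 expected. Of genes called without the arrays of 1 scan day, 91.8% (red light) and 93.7% (far-red against blue) had the same direction on that day (58.3% and 32.4% at least 2-fold), and the other comparisons allowed no such test.

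The seed series asked how transcripts changed from the dry seed through imbibition. At 24 h GASA6 (AT1G74670) rose from −6.36 ± 0.42 to 4.78 ± 0.28, 2260-fold (log2 11.14, SE 0.37, adjusted p = 1.7e-07), and the cell wall gene PDCB1 (AT5G61130) 404-fold (log2 8.66, SE 0.32). MAN1 (AT1G02310) fell from 2.96 ± 0.08 to −6.69 ± 0.11, a log2 change of −9.65 (SE 0.23), and the ABA biosynthesis gene NCED4 (AT4G19170) fell by 7.30 (SE 0.39). 8 of 12 germination genes rose, 1 fell and 3 did not pass (camera up, adjusted p = 0.0101, adjusted p = 0.364 with an estimated correlation), with EXPA2 (AT5G05290) up 6000-fold (log2 12.55, SE 0.65, 1 of 3 dryseed arrays well above background) and EXPA8 299-fold (log2 8.22, SE 0.21). 13 of 21 seed storage genes fell and 8 did not pass (camera down, adjusted p = 0.0033, adjusted p = 0.367 with an estimated correlation), with DOG1 (AT5G45830) down by log2 −5.51 (SE 0.59). 2 of 23 ABA-response genes rose, 16 fell and 5 did not pass (camera down, adjusted p = 0.00461, adjusted p = 0.383 with an estimated correlation), with HAI1 down by log2 −6.93 (SE 0.39). All 15 ribosomal protein genes rose (camera up, adjusted p = 2.95e-07, adjusted p = 0.439 with an estimated correlation). 11 of 18 root genes rose, 1 fell and 6 did not pass (camera up, adjusted p = 0.0428, adjusted p = 0.553 with an estimated correlation), with PYK10 (AT3G09260) up at least 588-fold. In all seed lists the counts adjusted over the list alone were the same. The feature NEW_TU_1458 (chromosome 2, 16803340 to 16803438, minus strand), 239 bp from the ABA factor gene ABI4 (AT2G40220), rose 26.1-fold (log2 4.70, SE 0.20). Of 22971 genes 5556 were higher and 5994 lower, or 4792 and 8059 by the median (shift −0.237) and 5453 and 5210 by quantile normalization (shift 0.182).

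At 48 h the photosystem gene PSAG (AT1G55670) had risen from −4.87 ± 0.54 to 7.01 ± 0.24, 3760-fold (log2 11.88, SE 0.34, adjusted p = 1e-08) over dry seed. HSP17.6A fell from 6.46 ± 0.06 to −7.60 ± 0.34, a log2 change of −14.07 (SE 0.64). All 26 photosynthesis genes rose (camera up, adjusted p = 6.74e-08, adjusted p = 0.369 with an estimated correlation), with RBCS2B up at least 13300-fold. 12 of 13 chlorophyll genes rose and 1 did not pass (camera up, adjusted p = 0.000567, adjusted p = 0.44 with an estimated correlation). All 21 seed storage genes fell (camera down, adjusted p = 2.08e-07, adjusted p = 0.17 with an estimated correlation), with CRU2 (AT1G03880) down by log2 −12.12 (SE 0.53). 15 of 16 cell cycle genes rose and 1 fell (camera up, adjusted p = 0.00044, adjusted p = 0.394 with an estimated correlation), with CYCD3;1 (AT4G34160) up at least 746-fold. 17 of 18 root genes rose and 1 did not pass (camera up, adjusted p = 0.000222, adjusted p = 0.327 with an estimated correlation), with CASP1 (AT2G36100) up at least 329-fold. The feature NEW_TU_1059 (chromosome 2, 18756626 to 18756841, plus strand) fell by 7.40 (SE 0.26) and NEW_TU_3670 (chromosome 1, 9952773 to 9952895, plus strand) fell by 7.16 (SE 0.22). Counts were 9317 higher and 7835 lower. With arrays scaled to the median, which moved the median of all genes by −2.04, they were 5568 and 13672, and by quantile normalization 8318 and 9065, so that the split at 48 h rests on the scaling.

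Between 24 and 48 h, FNR2 (AT1G20020) rose 4040-fold (log2 11.98, SE 0.47) and PRK (AT1G32060) 3010-fold (log2 11.56, SE 0.30), and CRU2 fell by 10.22 (SE 0.53). All 26 photosynthesis genes rose (camera up, adjusted p = 1.22e-09, adjusted p = 0.327 with an estimated correlation), and all 13 chlorophyll genes rose (camera up, adjusted p = 6.89e-05, adjusted p = 0.37 with an estimated correlation). 9 of 15 ribosomal protein genes fell and 6 did not pass (camera down, adjusted p = 0.000784, adjusted p = 0.605 with an estimated correlation). 20 of 21 seed storage genes fell and 1 did not pass (camera down, adjusted p = 2e-07, adjusted p = 0.17 with an estimated correlation). Counts were 8053 higher and 6389 lower, 4884 and 14271 by the median (shift −1.81), and 6946 and 8445 by quantile normalization (shift −0.335). 2 of 10 reference genes rose, 2 fell and 6 did not pass (camera adjusted p = 0.844) at 24 h and 3 of 10 reference genes rose, 1 fell and 6 did not pass (camera adjusted p = 0.968) at 48 h. UBQ10 fell by 3.00 and then fell by 4.92 from dry seed, downward under every scaling. EF1A (AT5G60390) rose by 1.04 at 48 h but fell with median scaling (adjusted p = 0.0013), and GAPC1 rose by 1.42 and 2.12 but turned to −0.27 and −0.39 with normexp. Effects of 24 and 48 h, which shared the dry seed arrays, correlated at 0.527, with a covariance of 4.1 (simulated 0.041). In both, 4149 genes rose against 2254 expected. Of genes called without the arrays of 1 scan day, 98.7% to 99.8% had the same direction on that day (9 values), and 80.6% to 96.3% changed at least 2-fold there.

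Among organs, neighbouring stages were compared. Rosette ages asked for transcripts of juvenile and of senescent leaves. Adult Rosette arrays spread widely, with pairwise distances (root mean square, log2) of 0.53, 0.819 and 1.01 (median within groups 0.305). In Young_Rosette the clock gene PRR5 was higher, at 4.00 ± 0.14 against −1.32 ± 1.07, 40-fold (log2 5.32, SE 0.32, adjusted p = 1.8e-14), and the cold gene COR15B (AT2G42530) 16.9-fold (log2 4.08, SE 0.47), while ERF11 (AT1G28370) was lower by log2 −5.86 (SE 0.42). 5 of 17 senescence genes fell and 12 did not pass, with 0 up and 6 down adjusted over the list alone (camera down, adjusted p = 0.00502, adjusted p = 0.357 with an estimated correlation), with WRKY53 (AT4G23810) down by log2 −3.77 (SE 0.46). 3 of 13 chlorophyll genes rose and 10 did not pass (camera up, adjusted p = 0.0244, adjusted p = 0.588 with an estimated correlation). UBQ10 and GAPC1 each fell by 1.88, downward under each scaling. Counts were 2199 higher and 2647 lower, with a shift of 0.131 by quantile normalization.

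In Old_Rosette the cation exchanger CHX17 (AT4G23700) was higher at 4.01 ± 0.24 against −3.68 ± 1.39, 206-fold (log2 7.69, SE 0.65, adjusted p = 1.8e-12), and the transporter AAT1 (AT4G21120) 201-fold (log2 7.65, SE 0.40). The pathogenesis gene PR1 (AT2G14610) stood at 6.21 ± 0.02 against −1.52 ± 3.00. The myrosinase TGG2 (AT5G25980) fell from 5.02 ± 0.46 to −4.55 ± 0.44, a log2 change of −9.57 (SE 0.73). 12 of 17 senescence genes rose, 2 fell and 3 did not pass (camera up, adjusted p = 0.00333, adjusted p = 0.327 with an estimated correlation), with SAG12 (AT5G45890) up at least 1930-fold and PPH (AT5G13800) by 4.30 (SE 0.28). 9 of 13 chlorophyll genes fell and 4 did not pass (camera down, adjusted p = 0.000176, adjusted p = 0.357 with an estimated correlation), with PCB2 (AT5G18660) down by log2 −5.48 (SE 0.39). 2 of 20 secondary wall genes rose, 16 fell and 2 did not pass (camera down, adjusted p = 1.93e-05, adjusted p = 0.299 with an estimated correlation). 8 of 11 mature pollen genes rose and 3 did not pass (camera up, adjusted p = 0.0109, adjusted p = 0.53 with an estimated correlation). Dim sORF features rose too (701 against 121 lower), so the rise need not be particular to pollen genes. 8 of 26 photosynthesis genes fell and 18 did not pass (camera down, adjusted p = 0.0101, adjusted p = 0.73 with an estimated correlation), with PSAD-2 (AT1G03130) down by log2 −3.32 (SE 0.23). 3 of 10 reference genes rose, 1 fell and 6 did not pass (camera up, adjusted p = 0.0348, adjusted p = 0.429 with an estimated correlation). Counts were 7394 higher and 6393 lower, or 9105 and 5335 by the median (shift 0.297) and 4147 and 4939 with normexp. No scan day or slide held both Rosette and another rosette age. Only for Old_Rosette can other organs and 1 Rosette array tell day from age.

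Flower development was followed from closed buds. In Bud, CYP71B31 (AT3G53300) was higher at −0.22 ± 0.25 against −5.53 ± 0.71, 39.7-fold (log2 5.31, SE 0.58, adjusted p = 6.5e-09), and the peptide gene LURE1.5 (AT5G43525) 23.3-fold (log2 4.54, SE 0.46), while A7 (AT4G28395) fell from 3.02 ± 0.42 to −4.64 ± 0.73. All 15 tapetum and pollen wall genes fell (camera down, adjusted p = 7.82e-19, adjusted p = 0.0115 with an estimated correlation), and MEE48 (AT4G14080) fell by 12.40 (SE 0.65, 1 of 3 Bud arrays well above background). 5 of 11 mature pollen genes rose and 6 did not pass (camera up, adjusted p = 0.00423, adjusted p = 0.492 with an estimated correlation), with VGDH1 (AT2G47030) up by 2.81 (SE 0.54). 1 of 20 secondary wall genes rose, 11 fell and 8 did not pass (camera down, adjusted p = 0.000336, adjusted p = 0.367 with an estimated correlation), with NST1 (AT2G46770) down by log2 −2.89 (SE 0.38). 4 of 13 callus and regeneration genes fell and 9 did not pass (camera adjusted p = 0.0626), with CUC1 (AT3G15170) down by log2 −2.86 (SE 0.38). 2 of 15 floral identity genes rose, 2 fell and 11 did not pass (camera adjusted p = 0.951). Counts were 2750 higher and 3175 lower, or 3274 and 2813 by quantile normalization (shift 0.156). In open flowers against Bud, HDG3 (AT2G32370) was higher at −0.15 ± 1.45 against −6.75 ± 0.25, 97-fold (log2 6.60, SE 0.66, adjusted p = 1.4e-09), and SAG12 66.1-fold (log2 6.05, SE 0.79), while SHN1 (AT1G15360) fell by 5.96 (SE 0.64). 7 of 17 senescence genes rose and 10 did not pass (camera up, adjusted p = 0.000131, adjusted p = 0.196 with an estimated correlation). 4 of 8 seed coat and endosperm genes rose and 4 did not pass (camera up, adjusted p = 0.00238, adjusted p = 0.309 with an estimated correlation), with BAN (AT1G61720) up 40.3-fold (log2 5.33, SE 0.62). Counts were 2147 higher and 1403 lower.

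Seed filling was followed in siliques. In Silique against Young_Silique, ENODL3 (AT4G28365) rose from −5.30 ± 0.06 to 2.80 ± 0.65, 275-fold (log2 8.10, SE 0.55, adjusted p = 7.5e-14), CSY1 (AT3G58740) 257-fold (log2 8.01, SE 0.49) and the stomatal protease SDD1 (AT1G04110) fell by 3.94 (SE 0.67). 16 of 20 secondary wall genes rose and 4 did not pass (camera up, adjusted p = 8.8e-13, adjusted p = 0.0734 with an estimated correlation), with CESA4 (AT5G44030) up by 3.63 (SE 0.34). 12 of 22 seed storage genes rose, 3 fell and 7 did not pass (camera up, adjusted p = 0.000734, adjusted p = 0.417 with an estimated correlation), with the embryo regulators LEC1 (AT1G21970) up by 5.62 (SE 0.58) and ABI3 (AT3G24650) by 5.43 (SE 0.61). 8 of 16 cell cycle genes fell and 8 did not pass (camera down, adjusted p = 0.000712, adjusted p = 0.485 with an estimated correlation). Counts were 3587 higher and 1681 lower, or 2515 and 2651 by quantile normalization (shift −0.114). In Old_Silique against Silique, BGLU19 (AT3G21370) rose from −5.34 ± 1.4 to 6.83 ± 0.61, 4620-fold (log2 12.18, SE 0.64, adjusted p = 4.8e-18), and the metallothionein AtMT4b (AT2G23240) 2720-fold (log2 11.41, SE 0.52), while GER3 (AT5G20630) fell by 9.19 (SE 0.81). 21 of 22 seed storage genes rose and 1 fell (camera up, adjusted p = 6.89e-10, adjusted p = 0.139 with an estimated correlation), with GEA6 (AT2G40170) up 20700-fold (log2 14.34, SE 0.70, 1 of 3 Silique arrays well above background). 16 of 17 senescence genes rose and 1 did not pass (camera up, adjusted p = 6.85e-06, adjusted p = 0.139 with an estimated correlation). 12 of 13 chlorophyll genes fell and 1 did not pass (camera down, adjusted p = 7.74e-05, adjusted p = 0.327 with an estimated correlation), and 1 of 20 secondary wall genes rose, 18 fell and 1 did not pass (camera down, adjusted p = 2.55e-08, adjusted p = 0.162 with an estimated correlation). 17 of 26 photosynthesis genes fell and 9 did not pass (camera down, adjusted p = 0.000877, adjusted p = 0.629 with an estimated correlation), with RBCS2B down by log2 −6.41 (SE 0.61). 1 of 8 seed coat and endosperm genes rose, 5 fell and 2 did not pass (camera adjusted p = 0.0871), with BAN down by log2 −8.37 (SE 0.62). The feature NEW_TU_2463 (chromosome 3, 19079028 to 19079126, plus strand) rose 96.3-fold (log2 6.59, SE 0.53) and NEW_TU_5084 (chromosome 4, 364147 to 364254, minus strand) fell by 7.92 (SE 0.56). UBQ10 rose by 3.50 and GAPC1 by 3.08, upward under each scaling. Counts were 6431 higher and 7715 lower, or 9758 and 5856 by the median (shift 0.513) and 7777 and 7255 by quantile normalization. Within scan days (4 values) and slides (2 values) of these flower and silique comparisons 83.3% to 100% of called genes changed at least 2-fold, but they had been called on the same arrays, and no scan day could be left out.

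Organ-highest genes asked which transcripts marked a single organ, and 4534 were found. They numbered 1292 in dry seed, 827 in Old_Rosette, 545 in roots, 380 in Young_Bud and 373 in callus, but 0 in Young_Rosette and Young_Silique, whose neighbouring stages were in the comparison. These counts depend on the settings, with 3543 in dry seed and 306 in roots by the median, 438 in Old_Rosette with the deposited values, and 131 in Young_Bud and 224 in callus with normexp. Seeds and scanner cannot be told apart among organs. Of all, 4143 were annotated and 202 sORF features. Dry seed was led by CCD7 (AT2G44990), 14.9-fold over the next organ, Old_Silique, and 14 of 26 heat shock genes were organ-highest. In roots the aquaporin TIP2;3 (AT5G47450) (6.55 ± 0.43) exceeded the next organ 324-fold and XTH21 (AT2G18800) 161-fold, and 3 of 20 genes of the root list were organ-highest, as many as in callus. In Young_Bud MEE48 exceeded the next organ 2750-fold, with 1 of 3 arrays of that organ well above background, and 12 of 15 tapetum genes were organ-highest. In callus the thioredoxin TH8 (AT1G69880) was 143-fold higher, and 4 of 13 genes of the callus list were organ-highest, WOX5 (AT3G11260), PLT1 (AT3G20840), PLT2 (AT1G51190) and CUC2 (AT5G53950). In stems 14 of 20 secondary wall genes were organ-highest, and FAR6 (AT3G56700) exceeded the next organ 49.1-fold with 2 of 3 arrays of that organ well above background. In Old_Silique CYP702A1 (AT1G65670) (2.57 ± 0.04) was 324-fold higher and DMP1 (AT3G21520) 47-fold.

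**Figure D4:**
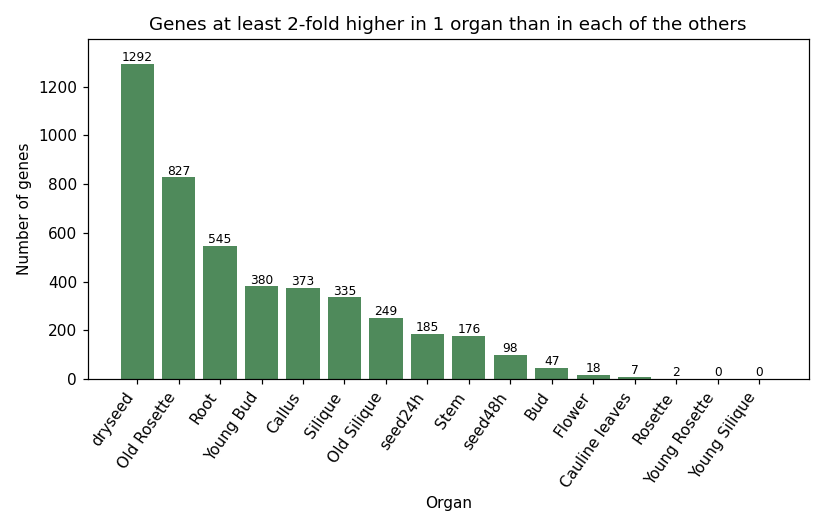
Number of genes at least 2-fold higher in 1 organ than in each of the 15 others (vertical axis), for 16 organs (horizontal axis), 3 arrays per organ. Dry seed had 1292 such genes, and Young_Rosette and Young_Silique 0.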

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

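The tests that weigh explanations in this part were all chosen after the results were seen, whereas the comparisons between times and colours had been planned. Those comparisons are listed as effects against 1 control differed by a test of the difference itself. The difference between 6 and 2 h concerned 5283 genes in drying, 2861 in salt, 4959 in heat and 1429 in cold. Between colours it concerned 206 genes for blue against red, 1393 for far-red against red and 441 for far-red against blue, and between 48 and 24 h of imbibition 14442 genes.

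The pattern at 1 h of white light was 0 called genes although sample 3 moved partly as at 6 h (correlation 0.693). CCA1 (AT2G46830), at 1.37, did not (sample 3 of 6 h, −1.22). BBX32 (AT3G21150) stood at −4.98, −5.57 and 4.57 in the 1 h samples, at −5.20, −5.61 and −3.77 in the 0 h samples, and at 1.18, 1.26 and 1.82 at 6 h. The 1 h samples numbered 1 and 2 lay 0.233 and 0.259 (root mean square, log2) from the 0 h samples of the same number. These were the closest 2 of 4752 pairs between groups, under the median within groups of 0.305, although on other slides and scan days. A scan-day difference hiding a response is argued against, since 0.641% of genes at most lay over 2-fold apart in these pairs, against 9.7% in the pair of a single day. A candidate explanation is that both samples hold RNA like that of 0 h, and a weak response to 1 h of light stays open, since the slope on the 6 h change was 0.303 in the pair numbered 3 alone, and no sample was reassigned.

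The pattern among sORF features was a correlation with the nearest annotated gene over the 33 group means, across features that are not independent. On the same strand within 1000 bp the median r was 0.329 in 515 pairs, against 0.179 in 564 pairs on the opposite strand. The difference was 0.15 (permutation p = 1e-05, two-sided, the smallest possible). Shared variation of neighbours stays open. The median's lower bound of 0.304 exceeded the upper bound of 0.114 for neighbouring annotated genes. So did the median of features beyond 1000 bp, 0.137, so these genes are no like control. Transcripts reaching over from the gene may explain part of these signals, as the median was 0.438 downstream and 0.152 upstream. NEW_TU_4296 (chromosome 1, 28798781 to 28798930, minus strand), 108 bp from AT1G76720, had r = 0.986, while shared regulation of separate transcripts was not tested.

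The pattern in heat was a surplus of rising sORF features, 432 against 89 falling at 2 h and 480 against 116 at 6 h, while 38.2% and 38.1% of called annotated genes rose. It was not particular to heat. At 2 and 6 h, 79.7% and 68.2% of called features (annotated 56.1% and 41.1%) rose in drying and 87.7% and 68.3% (68.2% and 49.3%) in salt. Cold gave no surplus (87.5% and 56.5%, annotated 87.3% and 58.5%). With normexp 51.7% rose at 6 h of salt and 75.9% at 6 h of cold, so that the surplus there rests on the settings. Scaling stays open, as at least 81.6% of called features rose under other settings, but none shifted heat down by over 0.029. A raised background can be part of the surplus, as sORF probes never detected rose by a median of 0.771 and 0.336. Subtracting these left 313 against 122 and 410 against 136. At most 31.4% of called annotated genes of like brightness rose, which cannot decide, since most called annotated genes fell in heat. A risen neighbour on the same strand lay by at most 16.4% of the risen features and cannot be the whole cause. Heat and Control shared no slide, and neither slide nor filter was tested. The filter can favour rises, as 526 of 1080 features but 20535 of 21809 annotated genes were detected in Control. These features may respond to heat, a hypothesis found and tested on the same samples.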

How the results depend on the processing

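Blocking by scan day, fixed slide blocks for light and organs, and omitting 1 h or number 3 arrays were chosen after seeing the data. The other alternatives were planned. A count was taken as kept within 1.5 times its value. Of 47 counts, 42 were kept with quantile normalization, 42 with the deposited values, 12 with normexp and 44 with replicate number as a block, all stress counts among these. Of 46 counts, 37 were kept with the median, 42 without a filter, 46 with every probe by itself, 40 with slide as a random block and 43 with 1 fit over 99 arrays. Every probe by itself did not test a choice of probe. The cause was not tested unless stated.

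Under normexp, counts of called genes were 3501 (dry2h), 6508 (dry6h), 2671 (Salt2h), 3427 (Salt6h), 4452 (Heat2h), 5850 (Heat6h), 551 (Cold2h) and 1598 (Cold6h) against Control, and 2561 (drying), 1373 (salt), 2304 (heat) and 757 (cold) for 6 against 2 h. They were 519 for Light6h, 592 for Red, 1122 for Blue, 1704 for FarRed, 57 for Blue against Red, 364 for FarRed against Red and 129 for FarRed against Blue. In organs they were 1856 (Young_Rosette), 9086 (Old_Rosette), 3360 (Bud), 1558 (Flower) and 2376 (Silique). The added offset of 50 pulls dim signals together by construction. Organ-highest genes under normexp numbered 53 in Silique, 137 in Old_Silique, 1 in Flower, Rosette and Cauline_leaves each, 131 in Young_Bud, 9 in Bud, 295 in Root, 103 in seed24h, 55 in seed48h and 224 in Callus.

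For Light6h, with 973 genes, 475 were called without a filter, 209 with slide as a random block, 1542 with scan day as a block, 2492 without arrays numbered 3 and 2607 in 1 fit over 99 arrays. The replicate block gave 2296, because white light samples of a number resemble each other. Light24h fell to 1489 with slide as a random block, and Cold2h to 815 in 1 fit over 99 arrays, while Silique against Young_Silique rose to 8080 without a filter.

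Blue against Red, with 206 genes, gave 78 without a filter, 584 with slide as a random block, 319 with the replicate block, 487 with scan day, 690 with slide as a fixed block and 690 without arrays numbered 3, and 133 by the median. FarRed against Blue gave 182 without a filter, 737 with the replicate block, 861 with scan day and 1431 without arrays numbered 3, which for FarRed against Red gave 2379. Slide as a fixed block gave 3527 for Red and 4353 for Blue, both resting on Dark 3 and Red 3, the only arrays that link Dark to a colour.

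Organ-highest genes by the median numbered 8 in Flower, 6 in Rosette, 14 in Cauline_leaves, 31 in Bud, 306 in Root, 3543 in dryseed, 1140 in seed24h and 51 in seed48h. By quantile normalization they numbered 30 in Flower, 4 in Young_Rosette, 104 in Bud, 512 in Old_Rosette and 3 in Young_Silique. By the deposited values they numbered 1 in Rosette, 1 in Young_Rosette, 82 in Bud, 438 in Old_Rosette and 3 in Young_Silique. Slide as a random block gave 3 in Flower, 1 in Cauline_leaves and 25 in Bud, and 1 fit over 99 arrays gave 1 in Young_Rosette. By the significance flag 4108 sORF features were detected against 2016, and 3 of 3 classes kept their count where 2 of 3 arrays sufficed. List shifts fell from 238 to 8 of 720 with an estimated correlation. The median signal of sORF probes, 2.31 units, limits their values.

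Leaving out 1 array at a time left all stress, seed and organ stage counts within 1.5 times, and the count of 0 for Light1h at 0. Light6h ranged from 351 to 896, with 568 and 489 without Light0h 1 and 2 and 382 and 351 without Light6h 1 and 2. Light24h ranged from 2055 to 2996, with 2055 and 2089 without Light24h 1 and 2. Blue against Red ranged from 58 to 295, with 62 and 86 without Red 1 and 2 and 58 without Blue 1 or Blue 2. FarRed against Red ranged from 867 to 1651, with 867 and 895 without Red 1 and 2. FarRed against Blue ranged from 122 to 699, with 122, 131 and 669 without Blue 1, 2 and 3 and 138, 164 and 699 without FarRed 1, 2 and 3. Organ-highest genes ranged from 5 to 20 in Flower (5 and 6 without Flower 1 and 2), 1 to 5 in Rosette (1 and 5 without Rosette 1 and 3), 2 to 3 in Cauline_leaves and 13 to 18 in Bud, each array of these last organs lowering the count.

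Directions that turned were few. Under normexp GAPC1 stood at −0.27 and −0.39 in seeds at 24 and 48 h, CYCB1;1 (AT4G37490) at −0.22, LAP6 (AT1G02050) at −0.02, SESA3 (AT4G27160) at −0.14, ABI5 (AT2G36270) at −0.14, PLT2 at −0.14 and LBD16 (AT2G42430) at −0.03 in Young_Rosette, CRC (AT1G69180) at −0.34 and LBD16 at −0.01 in Old_Rosette, FIS2 (AT2G35670) at −0.27 in Bud, EM1 at 0.07 in Flower, and NET2B (AT1G09720), organ-highest in Flower, at −0.22 over the next organ. By the median, seeds at 48 h had RPL23AB (AT3G55280) at −0.16, RPL23AA (AT2G39460) at −0.26 and EF1A at −1.0. With slide as a fixed block NEW_TU_6433 (chromosome 5, 970977 to 971072, minus strand) stood at −0.36 in FarRed, SESA3 at −1.75 in Old_Rosette and QRT3 (AT4G20050) at −0.06 in Silique. With scan day as a block CYP704B1 (AT1G69500) stood at 0.40, JAZ5 (AT1G17380) at 0.02 and JAZ8 at 0.21 in Old_Rosette, where 1 Rosette array carries the comparison, and the photosynthesis list turned upward in Light1h with an adjusted p of 0.95. Among tests of single named genes, 898 kept their call under normexp and 165 became weaker, against 1075 and 1 with the replicate block, and 5953 and 395 when 1 array was left out.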

Other observations

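The search for shared stress genes and the regroupings of arrays were chosen after the results were seen. In all 8 stress comparisons 193 genes were higher (156 annotated and 33 sORF features) and 9 lower. Among them CML37 rose by 4.50 (6 h of heat) to 7.77 (2 h of salt), MYBR1 (AT5G67300) by 4.47 (6 h of cold) to 9.75 (2 h of drying), the zinc finger genes RHL41 (AT5G59820) by 3.77 to 6.28 and STZ (AT1G27730) by 3.55 to 6.16, and the blue copper protein BCB (AT5G20230) by 3.65 to 5.86. All 8 share the 3 Control arrays of time 0, so that a chance dip in these or elapsed time can add to this overlap.

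Some arrays stood apart. In Silique 1 and 3, 36.7% and 32% of sORF probes were well above background, against 15.9% in Silique 2. The Rosette arrays had a 75th percentile of 194.6, 694 and 1183 units, and Young_Silique 1 and 2 were the closest pair of arrays at a distance of 0.069.

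Arrays were regrouped to ask how often chance gives as many genes. Comparisons of 3 with 3 arrays allow 10 splits, too few for a share under 0.05. The highest count of the other splits was 5 in stress against Control (real counts 1235 to 10140) and 37 in 6 against 2 h (cold, real 1429). It was 1 for Light1h (real 0). It was 0 in the other light and the seed comparisons, also in the splits that part all same-number pairs of white light and seed samples. In organs it was 1066 for Young_Rosette (real 4846), 5821 for Old_Rosette (real 13787, where the real split also parts scan days), 33 for Bud (5925), 107 for Flower (3550), 35 for Silique (5268) and 467 for Old_Silique (14146). With all arrays of an experiment regrouped 100 times, the real grouping called most genes over all comparisons, for stress (63082 against 22180), monochromatic light (10430 against 8553), organ stages (47522 against 2505) and organ-highest genes (4534 against 0). Arrays were also regrouped within their numbers, which mark scan days in stress and seeds and similar samples in white light. The real grouping again called most genes in stress (15255 in the highest other of 100), white light (4111 against 2565 in 100, freely regrouped 2313) and seeds (43144 against 25624 in 36, freely 25751). Chance was thus excluded for seeds. Stress, light and organ groups partly follow slides (6 h of salt, heat and cold shared none with Control), which no regrouping kept, so that chance was excluded there only apart from slides. For list shifts, 7 of 100 groupings gave as many as the real 238 (highest other 249), so that chance was not excluded for their number.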
